A study of Mus musculus with 6 samples.

How the data were processed

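RNA from 6 mouse lung metastases of MMTV-Myc tumours, in which a mammary promoter drives the Myc oncogene, was measured on Affymetrix mouse arrays. All animals were of the FVB strain. According to the labels, 3 metastases came from E2F2 knockout mice (KO) and 3 from mice heterozygous for E2F3 (Het). Metastases were taken at endpoint and flash frozen, and RNA was extracted on spin columns and labelled with biotin, per the labels' protocols. Metastases with both E2F genes intact were not analysed here.

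The values were intensities on a linear scale, deposited by the authors. MAS5 and Affymetrix Expression Console were named in the submitters' processing notes, and their versions were not given in the sources used here. Each deposited column had a trimmed mean of 500.2, which showed that the authors had scaled every array to a common level. MAS5 detection calls were not used here, so whether a dim probe set was above background was not known. The number of arrays limits the precision, and no depth applies to array signals.

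The table held 22690 probe sets, of which 64 were hybridisation or labelling controls. The platform annotation gave 1 gene symbol for 20380 probe sets, several for 691 and none for 1555. Of the probe sets with 1 symbol, 20351 were matched through the Entrez ID to a gene table of the GRCm38.p6 assembly, and 0 symbols needed an update. Probe sets with several symbols or none entered the tests but were not named. No coordinates are given, because the sources used here name no genome build for the values.

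The following choices were made before the data were examined. Signals were transformed to log2(signal + 16), so fold changes are on that scale and understate the change of dim genes. Controls and the 40% of probe sets with the lowest mean over the 6 arrays were left out, which kept 13575. The titles of the 3 Het arrays share the number 4421, whereas the 3 KO arrays carry 3 different numbers. The meaning of this number is not given in the sources used here. Because arrays sharing it probably came from the same mouse, the 3 Het arrays were averaged into 1 sample and compared with 3 KO samples. Probe sets were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), with Benjamini-Hochberg adjustment and a threshold of 0.05. The lone Het sample was assumed to vary like the KO samples. Nothing in the labels says that the samples came from separate animals, so the p-values measure only the spread between the KO samples, which may be partly technical.

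The 30 gene lists, with 651 genes in all, were also fixed in advance. They covered the E2F family, E2F and Myc targets, mammary and squamous differentiation, stroma, lung, blood and immune cells, and metabolic and stress pathways. Of these genes, 582 were on the array. Each gene was represented by its brightest probe set, giving 7957 genes. Lists with at least 3 genes were tested with camera of limma, with adjustment over the 29 lists tested. The correlation between genes was preset at 0.01, and in a second run it was estimated from the data. With the estimate, camera also refers its statistic to the residual degrees of freedom of the fit, which are few here. A list can then lose its call whatever its correlation. The T and NK cell list had 2 genes left and was not tested. SD is given over the 3 arrays of a group, and SE is that of the limma fit.

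Genes were named by a rule. The targeted genes came first. Next came 10 genes in each direction past the threshold, or, where too few passed, those with the largest moderated t among genes with a log2 difference of at least 1 and no overlap between the arrays of the groups. Up to 4 members with the largest moderated t were then taken from each list described. No probe set carried the symbol E2f2 in the annotation used here, so the level of E2f2 was not analysed here. A result for 1 gene taken by the rule is not reported here.

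The procedure was tested on simulated data with the spread of the 3 KO arrays over 13575 probe sets, of which 200 were changed in each of 5 runs. With 3 samples against 1, limma recovered 0% of probe sets changed by a log2 value of 1, 0.3% of those changed by 2 and 76.5% of those changed by 4. With each array as a sample, the shares were 40.4%, 81.9% and 96.5%. A list shifted by 0.5 was called by camera in 5 of 5 runs, and 8 calls of unshifted lists were also made over these runs, with 29 lists tested in each. Genes and arrays were drawn independently, whereas the correlation estimated within the lists of the real data reached 0.997 for MHC class II genes. The simulation therefore does not show how often camera calls lists wrongly in these data. The averaged Het sample varied less than a KO sample in the simulation, unlike the assumption of the fit. The simulation therefore also does not give the recovery, per array or with 3 samples against 1, if the Het arrays share a mouse.

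Alternatives covered the unit of replication, the pseudocount, the filter on dim probe sets, the normalization between arrays, the variance prior, the correlation between genes, the probe set per gene, and leaving out each array in turn. A fit without both KO replicate 1 and Het replicate 2 was added after seeing the data. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.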

Results

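Gene expression was compared between lung metastases of MMTV-Myc tumours from E2F2 KO mice and from E2F3 Het mice, with 3 arrays in each group. The comparison asks how metastases from mice labelled E2F2 knockout differ from those of mice labelled heterozygous for E2F3. E2F2 and E2F3 are both members of the E2F family of cell cycle transcription factors. All 6 arrays had the same trimmed mean signal of 500.2, and their median signals ran from 137.6 to 164.8. Het replicate 2 stood apart in its 3' to 5' signal ratios. Its ratio for actin was 2.38, against 1.48 to 1.73 on the other arrays, and its ratio for the transferrin receptor was 11.8, against 3.25 to 5.15. The ratios of spiked-in controls were raised on this array as well, with thr at 4.16, against 1.60 to 2.24; these are added from outside the sample.

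Myc, the driver of these tumours, was bright in both groups, with a signal of 11557 ± 1374 in KO and 12712 ± 1230 in Het metastases (SD, n = 3 arrays each). The log2 difference of KO minus Het was -0.14 (SE 0.20; limma adjusted p = 0.9999). E2f3 had a signal of 107 ± 26.8 in KO and 101.5 ± 37.7 in Het metastases (SD, n = 3 arrays each), a log2 difference of 0.09 (SE 0.39; limma adjusted p = 0.9999). The sign of the E2f3 difference turned to -0.02 with quantile normalization, to -0.08 without KO replicate 3 and to -0.09 without Het replicate 3. Whether this E2f3 probe set lies in the disrupted part of the gene is not known here, so it does not check the Het labels. The level of E2f2 was not analysed here, so the KO labels were not checked.

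Among single genes with a log2 difference of at least 1 and no overlap of arrays, Basp1, Muc4 and Gata3 had the largest moderated t of those lower in KO metastases. Muc4, a membrane mucin, had a signal of 64.1 ± 12.0 in KO and 278.2 ± 72.4 in Het metastases, and Gata3, a luminal transcription factor, had 389.6 ± 40 and 837.7 ± 187.6 (SD, n = 3 arrays each). Their log2 differences were -1.86 (SE 0.34) and -1.06 (SE 0.25), and that of Basp1 was -1.10 (SE 0.18). Adgrg3, Pnrc2, Eln, Rab17, Chst2, 2610528A11Rik and Ucp3 were also lower, with log2 differences between -1.004 for Pnrc2 and -1.62 for 2610528A11Rik. On the higher side, Deptor, an inhibitor of mTOR signalling, had 1518 ± 488 in KO and 482.6 ± 108.1 in Het metastases (SD, n = 3 arrays each), a log2 difference of 1.60 (SE 0.37). Dimmer probe sets of Deptor and Pnrc2 were at 0.51 and -0.57. The alarmin Il33 was higher by 1.35 (SE 0.27), Iffo2 by 1.85, Alox12e by 1.61, the platelet chemokine Ppbp by 1.43, Ago2 by 1.29, the kinesin Cenpe by 1.27, Fpr2 by 1.26 and Kdm5a by 1.21. Without Het replicate 1, the differences were 0.86 for Il33, 0.86 for Ago2 and 0.80 for Kdm5a.

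**Figure D1:**
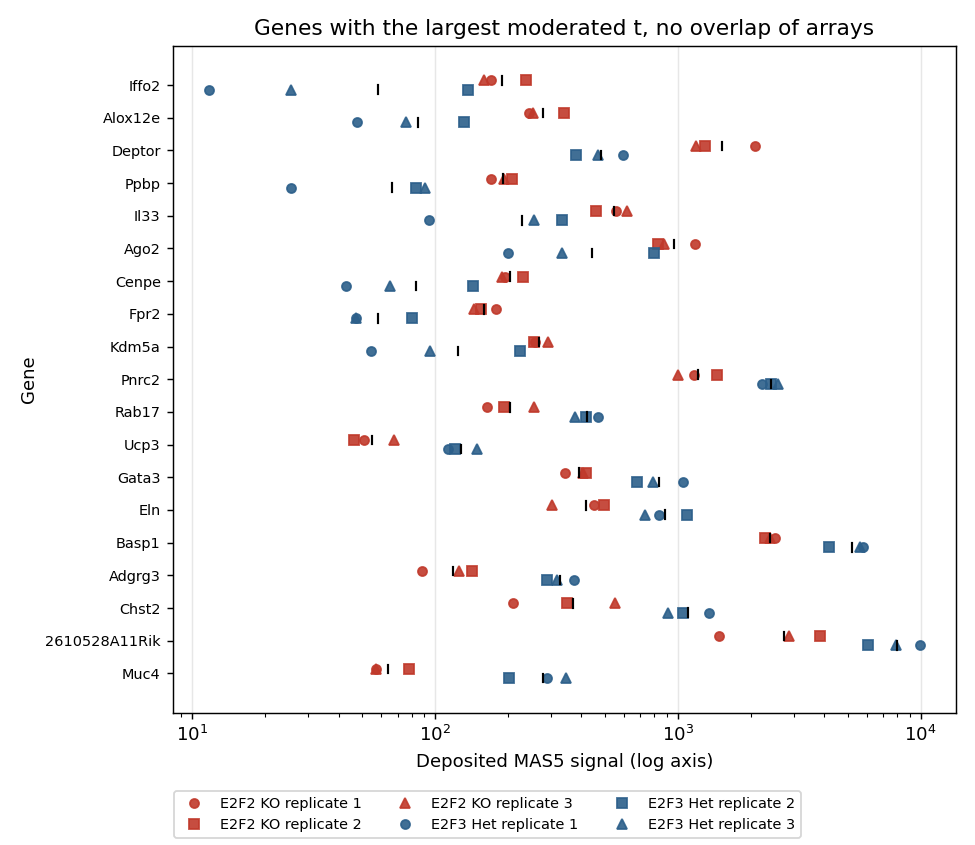
Deposited MAS5 signal (log axis) of 19 genes, 9 higher and 10 lower in KO. They had the largest moderated t among genes with a log2 difference of at least 1 and no overlap of arrays. Each symbol is an array, red for KO and blue for Het, with the shape giving the replicate, and black ticks mark group means; Muc4 lies at 56.9 to 78.0 in KO and 201.0 to 344.7 in Het.

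None of these 19 genes passed the test. With limma on 3 KO samples against the averaged Het sample, 0 of 13575 probe sets had an adjusted p under 0.05 (lowest 0.9999), and 301 had an unadjusted p under 0.05, against 679 expected by chance. The 301 are not read as fewer differences than chance. The averaged Het sample is a mean of 3 arrays, so the fit may overstate its variance and give p-values that are too large. With each of the 6 arrays as a sample, 0 passed (lowest limma adjusted p = 0.274) and 1394 had an unadjusted p under 0.05. Leaving out a KO array left fewer KO samples against the averaged Het sample. In that fit the number with an unadjusted p under 0.05 fell without KO replicate 2 and rose without KO replicate 3. The arrays of the groups did not overlap for 16.7% of probe sets, 1061 higher and 1209 lower in KO. Chance gives 10% if the 6 arrays are independent. With the title number as a random block, the fitted correlation of arrays sharing it was 0.31. Because these arrays are the whole Het group, this value reflects only the smaller spread among Het than among KO arrays. A correlation between arrays of 1 mouse could not be observed. It would raise the share given by chance, so the excess is not read as an effect of genotype. An exact test of 3 arrays against 3 cannot go below p = 0.1, and genotype cannot be separated from the mouse of origin if the Het arrays share a mouse.

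Genes of lipid and cholesterol synthesis were higher in KO metastases, in 18 of the 19 members measured. The mean log2 difference of the list was 0.53, with camera adjusted p = 2.1e-12 at the preset correlation. With an estimated correlation, the camera p was 0.026 and the adjusted p = 0.764. Sqle, which catalyses the first oxygenation of sterol synthesis, had a signal of 1673 ± 28.8 in KO and 890.5 ± 93.8 in Het metastases (SD, n = 3 arrays each). The log2 differences were 0.90 (SE 0.21) for Sqle, 0.89 (SE 0.31) for Fdps, which makes farnesyl diphosphate, 0.67 (SE 0.26) for the mevalonate pathway enzyme Hmgcs1, and 0.75 (SE 0.28) for the fatty acid elongase Elovl6. The arrays of the groups did not overlap for 10 of the 19 genes, and no member passed the test alone. This was the 1 list of the 29 tested whose array means did not overlap. They lay at 0.20 to 0.38 in KO and -0.37 to -0.13 in Het relative to the mean of the 6 arrays. Chance would give 2.9 such lists if the 6 arrays were independent.

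**Figure D2:**
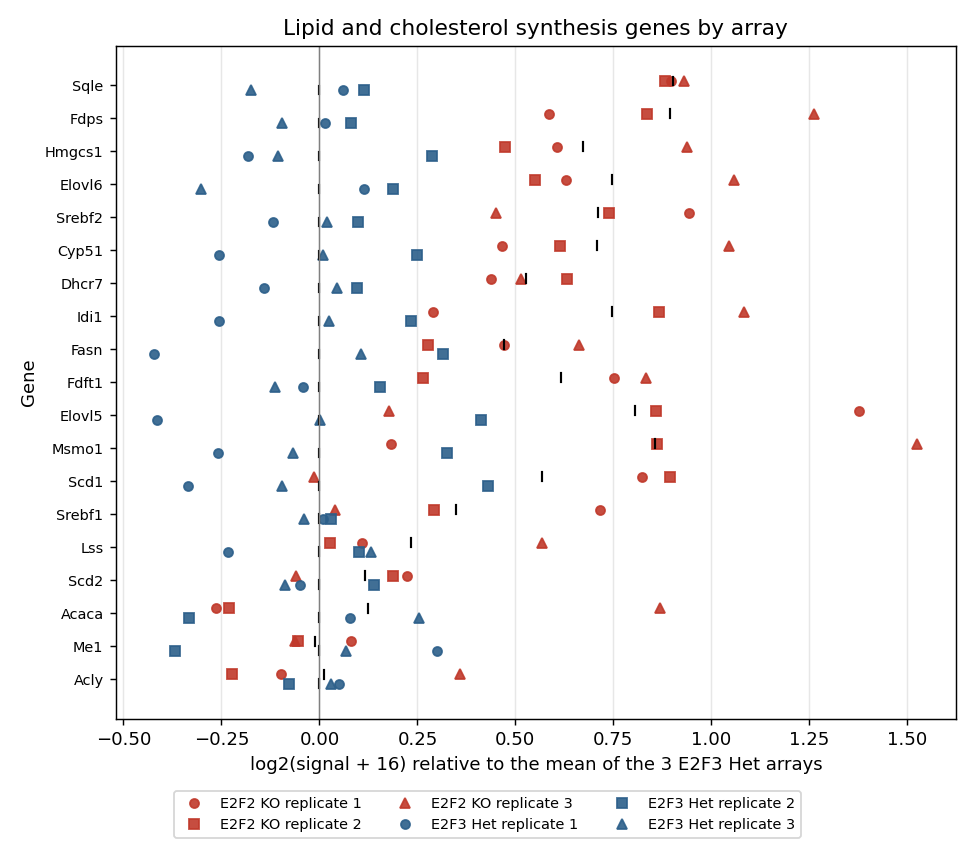
Log2(signal + 16) of the 19 measured genes of the lipid and cholesterol synthesis list, relative to the mean of the 3 Het arrays. Each symbol is an array, red for KO and blue for Het, with the shape giving the replicate, and black ticks mark group means; the groups do not overlap for 10 genes, and the KO mean of Sqle lies at 0.90.

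Genes of fibroblasts and extracellular matrix were higher in KO metastases in 17 of 21 members, with a mean log2 difference of 0.34 (camera adjusted p = 2.4e-05; adjusted p = 0.970 with an estimated correlation). The collagen genes Col1a1, Col6a3 and Col5a1 were higher by 0.95 (SE 0.27), 1.21 (SE 0.42) and 0.72 (SE 0.27), whereas Eln, which encodes elastin, was lower (-1.07, SE 0.34). Dimmer probe sets of Col1a1 and Col5a1 were at 0.23 and 0.29. The list mean was 0.19 without KO replicate 1 and 0.56 without KO replicate 3. Relative to the mean of the 6 arrays, the list lay at 0.46, 0.31 and -0.27 in KO replicates 1, 2 and 3, beside 1.33, 0.40 and -0.98 for lung alveolar genes and 0.67, 0.30 and -0.54 for endothelial genes. Genes of the epithelial-mesenchymal transition were higher in 11 of 14 members, with a mean of 0.39 (camera adjusted p = 5.6e-05; adjusted p = 0.878 with an estimated correlation). They included S100a4 (0.83, SE 0.34), the repressor of E-cadherin Zeb2 (0.92, SE 0.41), and the matricellular genes Ccn2 (0.56, SE 0.26) and Ccn1 (0.51, SE 0.25). This list lay at 0.32, 0.40 and -0.14 in the same KO replicates, so it was also lowest in the array with the lowest alveolar and endothelial values. Of the metastasis-related genes, 14 of 18 were higher, with a mean of 0.31 (camera adjusted p = 0.0046; adjusted p = 0.878 with an estimated correlation). The adhesion receptor Cd44 differed by 0.77 (SE 0.32), Id1 by 1.09 (SE 0.55), Fscn1 by 0.42 (SE 0.23) and Nme1, known as a metastasis suppressor, by 0.50 (SE 0.14). The difference was 0.27 for Nme1 without Het replicate 1 and 0.69 for Id1 without KO replicate 1. Dimmer probe sets were at 0.21 for Fscn1, 1.05 for Cd44 and 0.39 for Nme1. This list too was lowest in KO replicate 3 among the KO arrays, at 0.24, 0.35 and -0.14.

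MHC class II genes, which present antigen, were higher in KO metastases in 4 of 4 members, with a mean log2 difference of 1.503 (camera adjusted p = 0.00054; adjusted p = 0.878 with an estimated correlation). H2-Aa had a signal of 2319 ± 1585 in KO and 508.2 ± 218.3 in Het metastases (SD, n = 3 arrays each). The log2 differences were 1.92 (SE 0.91) for H2-Aa, 1.88 (SE 0.90) for the invariant chain Cd74, 1.34 (SE 0.65) for H2-Ab1 and 0.88 (SE 0.70) for H2-DMa, which was 0.47 without KO replicate 1 and 1.38 without KO replicate 3. All 4 were highest in KO replicate 1, the list lay at 1.69, 0.99 and -0.43 in KO replicates 1, 2 and 3, and the list mean was 0.84 with no filter on dim probe sets. The erythroid and platelet list had a mean of 0.61 (camera adjusted p = 0.0041; adjusted p = 0.878 with an estimated correlation). It lay at 0.59, 0.37 and -0.05 in KO replicates 1, 2 and 3, in the order of the alveolar and endothelial lists. Its higher members were the platelet genes Ppbp (1.43, SE 0.29), Pf4 (0.91, SE 0.46) and Itga2b (0.48, SE 0.33), whereas the erythroid gene Alas2 was at -0.38 (SE 0.63). Pf4 was 0.58 without KO replicate 1, and Alas2 was 0.09 without KO replicate 3. Ppbp was the 1 member of any list that passed when p was adjusted over the list alone, against 0 adjusted over all probe sets. This list was no longer called without Het replicate 1, with a mean of 0.30, or with no filter on dim probe sets, with a mean of 0.26.

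Lung alveolar genes had a mean log2 difference of 0.50, with 15 of 17 higher in KO (camera adjusted p = 0.0089; adjusted p = 0.970 with an estimated correlation). The water channel gene Aqp5 differed by 1.2 (SE 0.88), the surfactant protein gene Sftpd by 0.93 (SE 0.93), Etv5 by 0.70 (SE 0.38) and Cav1 by 0.39 (SE 0.32). Without KO replicate 1, these were 0.78 for Aqp5, 0.22 for Sftpd and 0.19 for Cav1, and without KO replicate 3, Aqp5 was 1.91 and Sftpd 1.5; Cav1 was 0.24 without Het replicate 1 and 0.65 without Het replicate 2. Of the 17 genes, 16 were highest in KO replicate 1, and the list mean ran from 1.33 in KO replicate 1 to -0.98 in KO replicate 3 relative to the mean of the 6 arrays. The list difference was -0.04 without KO replicate 1, 1.11 without KO replicate 3 and, no longer called, 0.33 without Het replicate 1. Endothelial genes had a mean of 0.28, with 17 of 19 higher in KO (camera adjusted p = 0.014; adjusted p = 0.970 with an estimated correlation). Sox17 differed by 1.05 (SE 0.63), Pecam1 by 0.61 (SE 0.48), Tie1 by 0.47 (SE 0.61) and Emcn by 0.45 (SE 0.38). Without KO replicate 3, Pecam1 was 0.95, Tie1 0.90 and Emcn 0.67, and without KO replicate 1, Tie1 was 0.21 and Emcn 0.30; Emcn was 0.20 without Het replicate 2. The endothelial call was lost without KO replicate 1 (mean 0.02), KO replicate 2 (0.20), Het replicate 1 (0.18) or Het replicate 3 (0.19), and the mean was 0.62 without KO replicate 3 and 0.48 without Het replicate 2.

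None of the 4 lists closest to the genotypes and to Myc was called. E2F target genes of S phase had a mean of -0.04 over 31 genes (camera adjusted p = 0.885), with Cdt1 at -0.32 (SE 0.21), Dnmt1 at -0.23 (SE 0.21), Prim1 at -0.21 (SE 0.21) and Tk1 at 0.27 (SE 0.27). This mean was 0.05 without KO replicate 1, and without Het replicate 1 Cdt1 was at -0.21 and Dnmt1 at -0.13. A dimmer probe set of Prim1 was at -0.04. Genes of G2/M and mitosis had a mean of -0.03 over 28 genes (camera adjusted p = 0.885), with Birc5 at 0.38 (SE 0.20), Mki67 at -0.37 (SE 0.27) and Bub1b at -0.35 (SE 0.30); without KO replicate 1, Mki67 was at -0.22 and Bub1b at -0.18. The E2F family and pocket proteins had a mean of 0.01 over 17 genes (camera adjusted p = 0.885). Within it, the cyclin gene Ccnd1 had a signal of 2550 ± 612 in KO and 1067 ± 541 in Het metastases (SD, n = 3 arrays each; log2 difference 1.34, SE 0.33), while Cdkn1b, Rb1 and E2f8 were at -0.44 (SE 0.25), -0.42 (SE 0.28) and -0.33 (SE 0.26). Myc target genes had a mean of 0.03 over 28 genes (camera adjusted p = 0.352), with Nop58 at 0.53 (SE 0.27), Eif4a1 at 0.33 (SE 0.14) and Bop1 at 0.28 (SE 0.24), which was 0.18 without Het replicate 1. Dimmer probe sets of Eif4a1 were at 0.48 and 0.08. Without KO replicate 1, camera called G2/M and mitosis (mean 0.11) and Myc targets (mean 0.11) as higher in KO at the preset correlation of 0.01. The correlation estimated in the main fit was 0.70 for G2/M and mitosis and 0.34 for Myc targets, and the estimate was not used without this array.

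Among differentiation lists, luminal epithelium had a mean of 0.01 over 19 genes (camera adjusted p = 0.885). Its members went both ways, with Gata3 lower and the pioneer factor Foxa1 higher by 1.08 (SE 0.38), Elf5 at -0.72 (SE 0.46) and Ehf at -0.40 (SE 0.22). The other 2 probe sets of Ehf were at 0.005 and 0.04, so 1 of 3 was lower, and a dimmer one of Elf5 was at -0.38. Without KO replicate 1, the list mean was -0.12 and Elf5 was at -0.39. Without both KO replicate 1 and Het replicate 2, the luminal list was called lower (-0.145). Basal epithelium had a mean of -0.12 (camera adjusted p = 0.885), with Lgr5 at -0.82 (SE 0.36), Itga6 at -0.54 (SE 0.24), Lama3 at 0.77 (SE 0.49) and Acta2 at 0.59 (SE 0.47). The sign of the basal mean turned to 0.17 without KO replicate 1 and to 0.07 without Het replicate 2, and without both the list was called higher (0.36, camera adjusted p = 0.010). Without KO replicate 3, Lama3 was at 0.47 and Acta2 at 0.94, and a dimmer probe set of Itga6 was at -0.18. Milk and secretory genes were lower in KO in 13 of 15 members, with a mean of -0.34 that did not pass (camera adjusted p = 0.057). It passed with the title number as a random block (camera adjusted p = 0.036) and with each array as a sample (camera adjusted p = 0.049), but had adjusted p = 0.970 with an estimated correlation. The mean was -0.89 without KO replicate 3, -0.06 without KO replicate 1 and -0.09 without KO replicate 2. Lactoferrin (Ltf) was at -1.14 (SE 0.74), Muc15 at -1.06 (SE 0.84), Xdh at -0.70 (SE 0.45) and Stat5a at -0.35 (SE 0.25). The other probe set of Stat5a went the other way, at 0.27. Ltf was at -1.73 without KO replicate 3, Muc15 at -0.40 without KO replicate 1, Xdh at -0.46 without KO replicate 2 and Stat5a at -0.15 without Het replicate 3. Genes of the unfolded protein response had a mean of 0.11 (camera adjusted p = 0.057). The mean was 0.18 and called without Het replicate 1 (camera adjusted p = 0.0067), 0.15 and called without KO replicate 1 (camera adjusted p = 0.013), and 0.06 without Het replicate 2. It was also called with quantile normalization and with 60% of dim probe sets left out, but had adjusted p = 0.878 with an estimated correlation. Its members included the stress regulator Atf4 at 0.66 (SE 0.19), Herpud1 at 0.83 (SE 0.29), Sel1l at 0.54 (SE 0.25) and Atf3 at -0.68 (SE 0.27). Dimmer probe sets were at 0.33 for Atf4, 0.89 for Herpud1 and 0.33, 0.90 and 0.38 for Sel1l. Immediate early genes had a mean of 0.08 (camera adjusted p = 0.530), with Fos at -0.81 (SE 0.21) and Ier3 at 0.87 (SE 0.33).

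Macrophage genes had a mean of -0.09 (camera adjusted p = 0.828), which was -0.26 and called without KO replicate 2 (camera adjusted p = 0.0066) and 0.09 without KO replicate 3. The list held Arg1 at 1.204 (SE 0.36), Ms4a7 at -1.03 (SE 0.51), Cd14 at -0.48 (SE 0.25) and Cd68 at -0.57 (SE 0.38). Squamous differentiation had a mean of -0.37 (camera adjusted p = 0.882) and the interferon response -0.40 (camera adjusted p = 0.772). Single arrays set the direction of both. Camera called the interferon list lower in KO without KO replicate 2 (mean -0.67), KO replicate 3 (-0.74) or Het replicate 1 (-1.21), and higher without KO replicate 1 (0.23) or Het replicate 3 (0.19). The squamous list was called lower without KO replicate 2 (-1.17), and its mean was 0.38 without KO replicate 1 and 0.40 without Het replicate 2. Without both KO replicate 1 and Het replicate 2 it was called higher (1.15). The interferon list held Psmb8 at 1.02 (SE 0.25), Psmb9 at 0.52 (SE 0.56), Ifit3 at -0.83 (SE 0.89) and Ifih1 at -0.57 (SE 0.61); without Het replicate 1, Psmb8 was at 0.41 and Psmb9 at -0.01, and without KO replicate 1, Ifit3 was at -0.12 and Ifih1 at -0.09. The means of the other lists tested were -0.25 for airway epithelium, 0.37 for neutrophils, -0.20 for B and plasma cells, -0.09 for hypoxia and glycolysis, -0.03 for the p53 pathway, -0.06 for oxidative phosphorylation, 0.14 for Wnt and Notch signalling, 0.31 for adipocytes and 0.40 for muscle. None of these 9 was called, and over the 19 lists with an adjusted p above 0.1 the camera adjusted p ran from 0.338 to 0.885. Several were called when an array was left out: airway epithelium (-0.74) and neutrophils (0.67) without KO replicate 1, adipocytes (0.79) without KO replicate 2, and muscle (1.01), hypoxia and glycolysis (-0.27), oxidative phosphorylation (-0.15) and Wnt and Notch signalling (0.30) without KO replicate 3. The camera direction was opposite to the mean for B and plasma cells, luminal epithelium and the E2F family, and the median of the Myc targets was 0.00 and below zero while the mean was above it.

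**Figure D3:**
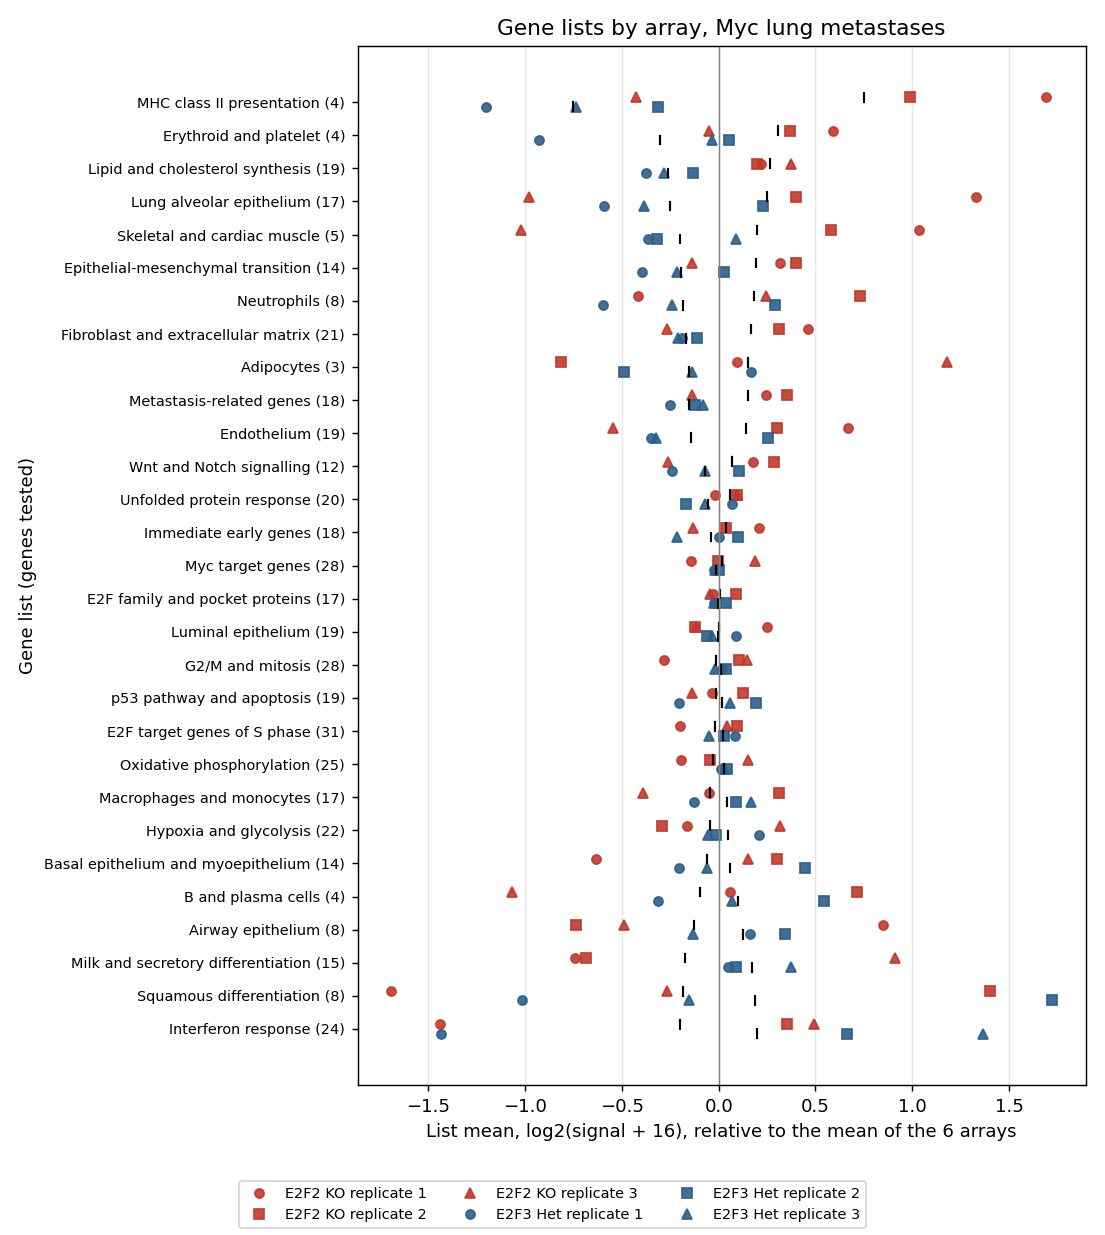
Mean log2(signal + 16) of the genes of each of the 29 lists tested on each array, relative to the mean of the 6 arrays. Each symbol is an array, red for KO and blue for Het, with the shape giving the replicate, black ticks mark group means and the number of genes is in parentheses; the lipid list shows no overlap between the groups, and the interferon list runs from -1.44 to 1.37 within Het.

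The spread among the 3 Het arrays, which share a title number, was set beside the spread among the 3 KO arrays, which do not. The median SD per probe set on the log2 scale was 0.22 for KO and 0.18 for Het metastases, a ratio of 1.22, and the SD was larger in KO for 59.5% of probe sets. Across probe sets, Pearson's r was 0.923 to 0.956 for pairs of KO arrays, 0.957 to 0.975 for pairs of Het arrays and 0.925 to 0.963 for pairs between the groups. Probe sets are not independent replicates, and no test was made of this difference.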

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

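The number of probe sets past the threshold was 0 under all 16 alternatives, with the lowest adjusted p between 0.274 and 0.9999. The number with an unadjusted p under 0.05 was 301, and was 1394 with each array as a sample, 677 with the title number as a random block and 162 (without KO replicate 2) to 944 (without KO replicate 3) when an array was left out. The fit without both KO replicate 1 and Het replicate 2 was chosen after seeing the data. The number of lists called was 8, and was 0 with an estimated correlation, 13 without both of these arrays and 7 to 14 when an array was left out, the highest without KO replicate 3.

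With an estimated correlation no list kept its call, at mean log2 differences of 0.53 (lipid), 0.34 (fibroblast and matrix), 0.39 (epithelial-mesenchymal transition), 1.503 (MHC class II), 0.61 (erythroid and platelet), 0.31 (metastasis-related), 0.50 (alveolar) and 0.28 (endothelium). Their adjusted p then lay between 0.764 and 0.970. Endothelium also lost its call with 60% of dim probe sets left out (0.24) and without both arrays (0.22), and ran from 0.018 to 0.623 when an array was left out. The alveolar list lost it without both arrays (0.20) and ran from -0.04 to 1.11. The erythroid and platelet list lost it with no filter (0.26) and ran from 0.30 to 0.79; with 60% of dim probe sets left out it had too few genes for a value. The lipid list ran from 0.47 to 0.59 and kept its call in 17 of 18 alternatives. Of the lists not called, 16 were called under some alternative, milk genes in 6 of 18, the unfolded protein response in 5 of 18, and interferon genes in 6 of 18, in 3 of them higher and in 3 lower. The cause of these differences was not tested.

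E2f3 turned to -0.021 with quantile normalization and ran from -0.086 to 0.338 when an array was left out, and it had no value with 60% of dim probe sets left out. Of 93 named genes, 6 changed sign under some alternative, and none of those named for the largest moderated t did; 34 moved by over 1.5 times when an array was left out. Without both arrays, Klk7 was at 1.17, Krtdap at 1.25, Ifih1 at 0.16 and Ifit3 at 0.15. When an array was left out, Klk7 ran from -2.26 to 0.10, Krtdap from -1.79 to 0.32, Alas2 from -0.862 to 0.092 and Psmb9 from -0.013 to 0.93. The ratio of spreads was 1.22 with a pseudocount of 64 and 1.26 with 60% of dim probe sets left out. No paired analysis was possible because the KO replicate numbers only name samples, whereas the Het numbers come from the titles.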

Other observations

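The tests of RNA quality (with its bounds on 4 ratios), macrophage content and T and NK cell content for the interferon genes, of both explanations for KO replicate 1, and of the single mouse behind the Het arrays were chosen after the values concerned had been seen. Metastases differed widely within the groups in interferon response genes, squamous genes and some milk genes, which were picked out after their values were seen. All 24 interferon genes were higher in Het replicate 3 than in Het replicate 1, 23 of them by at least 1 on the log2 scale, with a median fold of 7.22. The antiviral gene Oas1a had a signal of 4318 in Het replicate 3 and 328.0 in Het replicate 1, and Irf7 had 2355 and 113.7. Among KO metastases, 23 of the 24 were lower in replicate 1 than in both others, with Oas1a at 211.4, 1502 and 1941 in replicates 1, 2 and 3.

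The squamous keratin genes Krt6a, Krt6b and Krt16 were high in a single metastasis of each group, whereas Krt10 of the same list was not (127.1 in KO replicate 2 and 172.8 in Het replicate 2, against 127.8 to 165.5 elsewhere). Krt6a had a signal of 2210 in KO replicate 2 and 2913 in Het replicate 2, against 48.1 to 602.6 on the other 4 arrays, and Krt6b had 731.2 and 960.0, against 26.3 to 136.0. KO replicate 3 had the highest signal for several milk genes. Its signal for Glycam1, a milk mucin, was 16331, against 368.4 to 1275 on the other arrays, and that for the fatty acid binding protein Fabp3 was 6974, against 118.5 to 188.5. Btn1a1 had 2802, against 249.4 to 1079, and Csn1s2a 21383, against 1326 to 14223. Wap did not set it apart (9295, against 7217 to 9654 in Het), and the casein gene Csn2 was bright on all 6 arrays, at 12671 to 18776.

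Lipid and cholesterol synthesis genes were higher in KO metastases, and lung tissue and RNA quality were weighed as explanations. With the alveolar list as a covariate over the 6 arrays, the lipid difference was 0.54 (SE 0.07 across genes), against 0.53 without it, while the endothelial difference went from 0.28 to 0.00. With the actin 3' to 5' ratio as a covariate the lipid difference was 0.64 (SE 0.11). The median absolute difference of all probe sets then rose from 0.18 to 0.23, and the endothelial difference from 0.28 to 0.775. The first test argues against lung tissue as the whole cause. The second cannot decide about RNA quality, because this covariate widened differences in general and was set mostly by Het replicate 2. Leaving out any single array, Het replicate 2 among them, kept the lipid difference at 0.47 to 0.59. The Het arrays carry 1 title number; if it names a mouse, genotype and that mouse cannot be told apart, and either may underlie the difference.

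Alveolar and MHC class II genes were highest in KO replicate 1. The lists of lung cell markers were fixed before the data were examined, and because the tissue was lung metastasis all of their genes may come from the lung around the tumour. If lung tissue were the source, airway genes should also be highest there, and 5 of 8 were, beside 16 of 17 alveolar genes. The surfactant genes Sftpa1 and Sftpc reached 12713 and 18127, although Sftpc was at 18596 in KO replicate 2. Of endothelial genes 15 of 19 were highest in KO replicate 1, but of macrophage genes only 4 of 17. On other arrays airway and alveolar genes parted. The airway list lay at -0.74 in KO replicate 2 and 0.16 in Het replicate 1, where the alveolar list lay at 0.40 and -0.59. The airway count goes with lung tissue in KO replicate 1 but does not settle it. An interferon response as the source of the MHC class II signal is argued against, since the interferon list in that array lay at -1.44 (SE 0.18 across genes) relative to the mean of the 6 arrays. No other biological explanation was tested.

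Interferon genes differed among the Het metastases by 2.81 on the log2 scale (SE 0.21 across genes) between the highest and the lowest array. Over the 13575 probe sets, the median absolute log2 difference between these 2 arrays was 0.20, and 309 differed by at least 1. Of the 24 interferon genes, 23 differed by at least 1. This argues against a general effect of RNA quality on the signals as the cause. The 3' to 5' ratios did not decide by themselves. Those of actin differed by 0.057, but those of the transferrin receptor were 5.15 and 3.25 and those of Pc 6.58 and 3.72. Het replicate 2, with the highest ratios, was to lie at one end if RNA quality were the cause and lay between them at 0.66, and KO replicates 1 and 3, at -1.44 and 0.50, had transferrin receptor ratios of 4.26 and 3.48 but Pc ratios of 2.27 and 5.84, so the measures pointed different ways. Macrophage content is argued against, because the macrophage list differed by 0.29 (SE 0.14). The T and NK list differed by 1.01, but over only 2 genes, so T and NK cell content stays open, and the design names no biological difference within Het.

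Other choices of the lone title number were also run. With the real choice, 301 probe sets had an unadjusted p under 0.05, and the highest of the other choices gave 1114; all 4 choices gave at least as many as the real one. Lists called numbered 8 with the real choice and up to 19 with another, again in all 4 choices. With 3 arrays against 3, the real split gave 1394 probe sets and the highest of the others gave 1392, so 1 of the 10 splits gave as many. These splits are too few for a share under 0.05. The 4 choices are also unlike, because the real lone sample was the mean of 3 Het arrays and each other lone sample was 1 array. A lone array is noisier than a mean, which favours larger counts. The lipid list's mean difference, others minus the lone sample, was 0.53 with the real choice. It was -0.12, -0.085 and -0.33 with KO replicate 1, 2 or 3 alone. Setting KO replicate 1, 2 or 3 alone gave 1114, 317 and 961 probe sets; a lone array does not enter the estimate of the spread, so these counts are not read as structure of the samples.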
